A study of Homo sapiens with 7 samples.

How the data were processed

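Total RNA from 7 human cell cultures was labelled with biotin and hybridised to Illumina bead arrays, 1 array per culture. The cultures were fetal astrocytes at early passage (2 arrays, passages 1 and 2, from 2 suppliers), fetal astrocytes at late passage (1 array, passage 9, from the supplier of the passage 2 cells), neural stem cells (2 arrays, cell lines NCRM5 at passage 14 and H9 at passage 8) and pluripotent stem cells (2 arrays, NCRM5 at passage 21 and H9 at passage 61). The labels call the early-passage, neural stem cell and pluripotent arrays biological replicates, and give both pluripotent arrays the number 1; here the H9 one was numbered 2 by order. The labels do not say whether the cells of passages 2 and 9 came from 1 donor. In the scanner table's column names the pluripotent H9 array carries the word for induced cells, where its labels say embryonic stem cells, and the NCRM5 arrays carry another name; columns were matched to samples by cell type and passage, and the labels were followed.

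The scanner table holds an intensity per probe and array, the mean bead signal, which is neither background-subtracted nor normalized between arrays, per the file headers and the values. It also holds a detection p-value per probe and array, per the file headers. GenomeStudio was used, per the submitters' processing notes, and its version is not given in the sources used here. A second deposited table holds the authors' normalized intensity. Its values were found to be on a linear scale and background-subtracted (lowest value -25.7), with near-identical distributions (medians 8.64 to 8.73), as quantile normalization gives. Each of its columns had a rank correlation of 1.000 with the scanner column of the same array. The authors' method is not stated beyond the tool.

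Of 47322 probes, 30112 carry 1 gene symbol in the platform annotation used here, 8 carry several and 17202 are unnamed here. Symbols were checked by gene number against a RefSeq gene table, which changed 0 of them and lacked the gene of 39 probes. The 144 probes of sex-linked genes that could point to a person's sex were left out. No genome coordinates were used.

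The main values were computed from the scanner intensities with the neqc function of limma 3.58.1 in R 4.3.3: normexp background correction based on the detection p-values, an offset of 16, quantile normalization and log2. A probe was tested where its detection p was below 0.01 on at least 2 of the 7 arrays, which left 15360 probes of 11673 genes. Of the 3044 genes with several tested probes, the probe with the highest mean stood for the gene. Probes of 1 gene were called in opposite directions for RCAN2 in the first comparison, TUBA1C in the second, and MLC1 and YTHDC1 in the third.

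All 7 arrays entered 1 limma fit (lmFit and eBayes) with 4 group means, 3 residual degrees of freedom and 6.54 after moderation, with a prior SD of 0.385. P-values therefore rest on a spread shared by the groups, and the single late-passage array was assumed to vary like the others. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, and every adjusted p given for a gene is from this limma fit unless another is named. Where no probe of a gene was above background on any array of the lower group, the fold is given as "at least": the brighter group's mean against the mean of, per array, the higher of the lowest log2 value among detected probes and the dim probe's own value. For HLA-DRA the bound was taken for the tested probe alone. Folds of other dim genes depend on the offset.

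Gene lists, the rule for the genes named, the comparisons, the tests and most alternatives were fixed before the data were examined. Per comparison, the named genes were the 6 with the largest rise and the 6 with the largest fall among called genes whose arrays did not overlap between groups, up to 3 called members of each list (or the 2 with the smallest p), and a fixed set of marker genes. The 20 lists were astrocyte, neural stem and progenitor, pluripotency, neuronal, oligodendrocyte, mesenchymal and matrix, endothelial and pericyte, microglia, neural crest, mesoderm and endoderm, HOX, cell cycle, senescence and secreted factors, interferon and MHC class I, Notch, cholesterol synthesis, metallothionein and antioxidant, glycolysis and hypoxia, stress and early response, and housekeeping. Genes that sit on 2 lists include HES5, NOTCH1 and DLL1 (progenitor and Notch), NOTCH3 (endothelial and Notch) and PGK1 (glycolysis and housekeeping). Lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01), adjusted over the 72 tests of 18 lists in 4 comparisons. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera refers its statistic to the residual degrees of freedom of the fit (3 here). A call lost that way need not reflect correlated genes. For the progenitor list between neural and pluripotent stem cells the estimated correlation was -0.00286, below the preset. Its unadjusted camera p still went from 3.43e-06 to 0.0139. Of the 27 list calls, 0 held with the estimated correlation and 6 with fry, which tests whether the genes of a list move 1 way on balance and does not compare them with other genes. The 6 were the pluripotency list (limma fry adjusted p = 0.00812) and the progenitor list (adjusted p = 0.0173) between neural and pluripotent stem cells, both lists between early-passage astrocytes and pluripotent cells (adjusted p = 0.00726 and 0.0107), and the senescence and secreted factor list in early-passage astrocytes against neural stem cells (adjusted p = 0.0107) and against pluripotent cells (adjusted p = 0.00921).

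Of the groups that share replicate numbers, early-passage astrocytes and neural stem cells share only numbers: deviations of same-numbered arrays from their group means had a correlation across genes of -0.00447. Neural and pluripotent stem cells share the cell lines NCRM5 and H9, which pairs them (correlation 0.109). Both blocks were fitted as alternatives. Other alternatives were no background correction, median scaling without the quantile step, the authors' normalized values, other detection filters, an offset of 50, the mean of a gene's probes, eBayes with trend and robust settings, a minimum log2 change of 1, only the 2 groups compared, all 3 astrocyte arrays as 1 group, and leaving out each array of a comparison in turn. When an array was left out, normalization was kept and the array was dropped from the fit; a group then left with 1 array was assumed to vary like the others. Chip as a block was not run, since neither labels nor column names give a chip.

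The test was tried on simulated data for 11673 genes with the fitted spread, 200 of them changed. For early-passage astrocytes against neural stem cells it called 0% of genes changed by 1 on the log2 scale, 20% of those changed by 2, 84% of those changed by 4 and 98% of those changed by 6, with 3 false calls. For the late-passage array against the early-passage arrays the shares were 0%, 4%, 64% and 88%, with 5 false calls. For neural against pluripotent stem cells they were 0%, 22%, 90% and 92%, with 7 false calls, and for early-passage astrocytes against pluripotent stem cells 2%, 30%, 92% and 100%, with 5 false calls. The first 3 comparisons called 555, 1614 and 2230 genes, more than the 200 changed in the simulation, so their adjusted cutoff was less strict. The simulated shares therefore do not give the sensitivity of those comparisons. There the smallest log2 changes called were 1.45, 1.15 and 1.05. The late-passage comparison called 0 genes, so its adjusted cutoff was stricter than in the simulation. Its simulated shares are therefore too high for the real data, where GFAP was not called at a log2 difference of -6.60. The number of arrays limits the precision throughout.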

Results

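Gene expression was measured in human fetal astrocytes, neural stem cells and pluripotent stem cells, with 7 arrays in 4 groups. NCRM5 is an induced pluripotent stem cell line and H9 an embryonic stem cell line; each was measured both as pluripotent cells and as neural stem cells. The question set by the series is how fetal astrocytes differ from neural stem cells made from pluripotent cells. Between 14734 probes (pluripotent H9) and 17772 probes (early-passage astrocytes, passage 1) were detected per array, and the mean signal lay between 3.44 and 5.31 times background on those same arrays. Across 11673 genes, which are not independent replicates, the 2 early-passage arrays had a Pearson r of 0.946, the 2 neural stem cell arrays 0.944 and the 2 pluripotent arrays 0.919. The late-passage array had an r of 0.930 with the passage 1 array and 0.941 with the passage 2 array. The first principal component (49.1% of the variance) ran from the astrocyte arrays to the pluripotent arrays, and the second component set the neural stem cells apart.

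**Figure D1:**
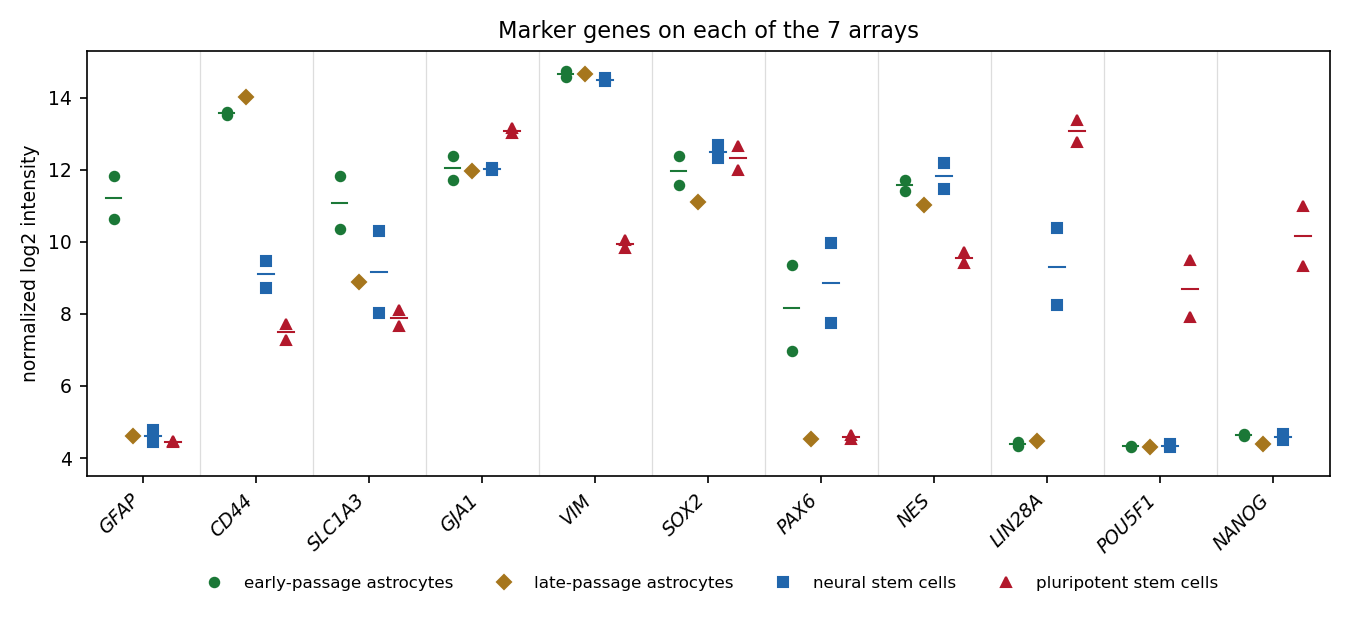
Normalized log2 intensity (vertical axis) of 11 marker genes (horizontal axis) on each of the 7 arrays; each symbol is 1 array and each short line the mean of a group of 2. GFAP lies at 11.82 and 10.62 in the early-passage astrocytes and at 4.62 on the late-passage array, while POU5F1 and NANOG stand above the rest in the pluripotent cells.

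Early-passage astrocytes differed from neural stem cells in genes that included 4 of 23 astrocyte list members. GFAP, the intermediate filament protein of astrocytes, had a log2 intensity of 11.22 ± 0.85 (SD, n = 2) in early-passage astrocytes and 4.62 ± 0.23 (SD, n = 2) in neural stem cells. It was not above background in neural stem cells and was at least 54.8-fold higher in astrocytes (adjusted p = 0.00207). NFIX, a transcription factor of glial development, was at least 67.0-fold higher (adjusted p = 0.00207), and CD44, a hyaluronan receptor, was 22.1-fold higher (log2 4.47 ± 0.37, SE; adjusted p = 0.00412). The largest rise was that of the chemokine CCL2, at least 233-fold (adjusted p = 0.000861), and HLA-DRA, an MHC class II chain, was at least 98.8-fold higher (adjusted p = 0.000934) by a probe not above background in neural stem cells, where another probe of the gene was. In the other direction, the RNA-binding proteins LIN28B and LIN28A, known from early embryonic cells, were at least 28.4-fold and at least 14.9-fold lower in astrocytes (adjusted p = 0.00551 and 0.0133). Without the passage 1 array LIN28B and LIN28A were not called (adjusted p = 0.0589 and 0.105), nor was LIN28A without the passage 2 array (adjusted p = 0.0864), without background correction (adjusted p = 0.0575) or without a detection filter (adjusted p = 0.0521). With the late-passage array added to the astrocyte group, GFAP was not called (adjusted p = 0.206).

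In all, limma called 555 of 11673 genes, 364 higher and 191 lower in early-passage astrocytes. Among the largest changes were also LHX2, a forebrain homeobox gene (at least 109-fold higher), DLK1, a Notch-related membrane protein (at least 99.5-fold higher), and OCIAD2 (124-fold higher). The largest falls included the secreted neuropeptide precursor VGF (72.8-fold lower), the calcium sensor NCALD (56.1-fold lower), the glutamate receptor GRM3 (55.3-fold lower), IGDCC3 (48.4-fold lower) and FAM181A (at least 27.1-fold lower). Leaving out 1 array lowered the count to 101 (without the passage 1 astrocytes), 218 (without the passage 2 astrocytes), 256 (without NCRM5 neural stem cells) or 217 (without H9 neural stem cells). Of 41 named genes called in this comparison, 14 stayed called whichever array was left out: CCL2, LHX2, DLK1, NFIX, OCIAD2, HLA-DRA, IGDCC3, FAM181A, GFAP, CD44, EMX2, TAGLN3, PRRX1 and IGFBP7. Whichever array was left out, 8 were not called: AURKB, COL6A3, DUSP1, EOMES, MCAM, PFKP, SOX3 and SQLE (adjusted p between 0.0531 and 0.248).

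Of 23 measured members of the astrocyte list, 4 rose (GFAP, NFIX, CD44 and HEPACAM), 0 fell and 19 were not called, with 6 higher and 0 lower adjusted over the list alone. The list as a whole lay higher in astrocytes by camera (median log2 1.09, or 0.81 with genes below background at their bounds, adjusted p = 0.000185). With an estimated correlation the call was lost (adjusted p = 0.273). Members that were not called included the filament protein VIM, with a log2 difference of 0.16 ± 0.29 (SE), and the gap junction protein GJA1, with 0.03 ± 0.34 (SE). The glutamate transporter SLC1A3 differed by 1.92 ± 0.81 (SE, adjusted p = 0.256). S100B, ALDH1L1, GJB6 and CLU were detected on 0 of the 7 arrays, and AQP4, SLC1A2 and AGT on 1. The neural stem and progenitor list split, with LHX2 and EMX2 (at least 21.1-fold) higher, SOX3 (13.5-fold) and ZBTB16 lower and 22 of 26 members not called (3 higher and 3 lower adjusted over the list alone). Its median was -0.38 and its mean 0.04, opposite in sign, and camera gave an adjusted p of 0.530. SOX2 (log2 difference -0.52 ± 0.41, SE), PAX6 (-0.69 ± 0.95, SE) and the progenitor filament NES (-0.26 ± 0.36, SE) were not called.

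Some neuronal and pluripotency genes were lower in astrocytes than in neural stem cells. Of 15 neuronal members, TAGLN3 (26.4-fold), the neuronal RNA-binding protein ELAVL3 (16.5-fold) and the synaptic vesicle protein SYT1 (7.61-fold) fell in astrocytes. None rose, and 9 were lower adjusted over the list alone. The neuronal list had a median of -2.19 (camera adjusted p = 0.000301, or adjusted p = 0.333 with an estimated correlation). Of 23 pluripotency members, 5 fell (LIN28A, LIN28B, SALL4, DNMT3B and PODXL), also 5 adjusted over the list alone. The other 18 included POU5F1 and NANOG, with log2 differences of -0.01 and 0.06. That list had a median of -0.09 and a mean of -1.09 (camera adjusted p = 0.0203). Its call was lost without the passage 1 array (adjusted p = 0.0548) and with an estimated correlation (adjusted p = 0.466). The cell cycle list had 0 of 29 members above 0 and a median of -0.90 (camera adjusted p = 1.20e-07, or adjusted p = 0.466 with an estimated correlation). Its 1 called member was the mitotic kinase AURKB (2.89-fold lower), with 0 adjusted over the list alone. The cholesterol synthesis list had a median of -1.07 (adjusted p = 0.000107, or adjusted p = 0.650 with an estimated correlation). SQLE, an enzyme of sterol synthesis, was called out of 17 members (3.49-fold lower), with 3 lower adjusted over the list alone.

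Of 29 mesenchymal and matrix members, 6 rose and 0 fell, with 13 higher adjusted over the list alone. The collagen chains COL1A1 (71.3-fold) and COL6A3 (at least 35.3-fold) and the matrix protein POSTN (26.4-fold) were among them. COL6A3 was not called without the passage 1 array (adjusted p = 0.125), the passage 2 array (adjusted p = 0.0659), the NCRM5 array (adjusted p = 0.0650) or the H9 array (adjusted p = 0.0626), nor without a detection filter (adjusted p = 0.0608). The list had a median of 1.86, or 1.43 at bounds (camera adjusted p = 2.25e-07, or adjusted p = 0.384 with an estimated correlation). Of 17 members of the senescence and secreted factor list, 5 rose, 8 adjusted over the list alone, among them CCL2, IGFBP7 (39.2-fold) and the cell cycle inhibitor CDKN2B (16.2-fold). Its median was 0.84, or 0.67 at bounds (adjusted p = 5.36e-06, or adjusted p = 0.208 with an estimated correlation). Of 23 interferon and MHC class I members, 10 rose, with 15 higher and 1 lower adjusted over the list alone. They included the interferon-induced MX1 (at least 10.1-fold) and IFI44 (at least 5.89-fold) and the immunoproteasome subunit PSMB8 (at least 4.67-fold). This list had a median of 1.87, or 1.74 at bounds (adjusted p = 4.16e-09, or adjusted p = 0.424 with an estimated correlation).

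The stress and early response list had 3 of 16 members called higher, the chaperones HSPA1A (24.4-fold) and HSPB1 (6.21-fold) and the phosphatase DUSP1 (5.39-fold), and 6 adjusted over the list alone. The stress list had a median of 1.60 (adjusted p = 0.000260, or adjusted p = 0.273 with an estimated correlation). The metallothionein and antioxidant list lay higher by camera (median 1.20, adjusted p = 0.000700, or adjusted p = 0.695 with an estimated correlation). None of its 19 members was called, also adjusted over the list alone, and HMOX1 had a log2 difference of 2.22 ± 0.49 (SE, adjusted p = 0.0585).

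Markers of other cell types were mixed where measured, and many were below the detection filter. Of 10 oligodendrocyte members, the progenitor receptor PDGFRA (at least 31.8-fold) and MBP (20.1-fold) rose, with 3 higher adjusted over the list alone. MBP was also 9.66-fold lower in neural than in pluripotent stem cells. OLIG2 lay at 4.74 at passage 1 and 9.12 at passage 2. SOX10, MOG, MAG, GPR17, OPALIN and MOBP were detected on 0 of the 7 arrays. The oligodendrocyte list's call (median 1.62, or 1.36 at bounds, adjusted p = 0.0335) was lost without the H9 neural stem cells (adjusted p = 0.211), without the passage 2 astrocytes (adjusted p = 0.148) and with an estimated correlation (adjusted p = 0.536). Of 8 neural crest members PRRX1 rose (at least 23.2-fold), with 2 higher adjusted over the list alone. The neural crest list was not called (adjusted p = 0.312) except without the H9 neural stem cells (adjusted p = 0.0474). Of 9 endothelial and pericyte members MCAM rose (at least 2.06-fold), with 1 higher and 1 lower adjusted over the list alone (list adjusted p = 0.568). Below the detection filter were 9 of the list's 18 members, with PECAM1, VWF and CLDN5 detected on 0 arrays. None of 4 measured microglia members was called, also adjusted over the list alone, CD14 having a log2 difference of -1.01 and CSF1R of 0.91. The other 12 of 16 were below the filter, with PTPRC, P2RY12 and TREM2 detected on 0 arrays. Of 3 measured mesoderm and endoderm members EOMES was called (at least 1.64-fold higher), with 2 higher adjusted over the list alone, and 15 of 18 were below the filter. The microglia list and the mesoderm and endoderm list were too short to test.

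Among the remaining lists, 0 of 9 HOX members were called, also adjusted over the list alone (list adjusted p = 0.872). The HOX list was called higher in astrocytes without the NCRM5 neural stem cells (adjusted p = 0.0252) and lower without the H9 neural stem cells (adjusted p = 0.00165). The Notch list had 0 of 19 called, with 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.185, or 0.00438 without the H9 neural stem cells). The housekeeping list had 0 of 13 called, also adjusted over the list alone (adjusted p = 0.690). In the glycolysis and hypoxia list (adjusted p = 0.208) PFKP was 5.20-fold higher and the glucose transporter SLC2A3 7.70-fold lower out of 21, the same counts adjusted over the list alone.

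**Figure D2:**
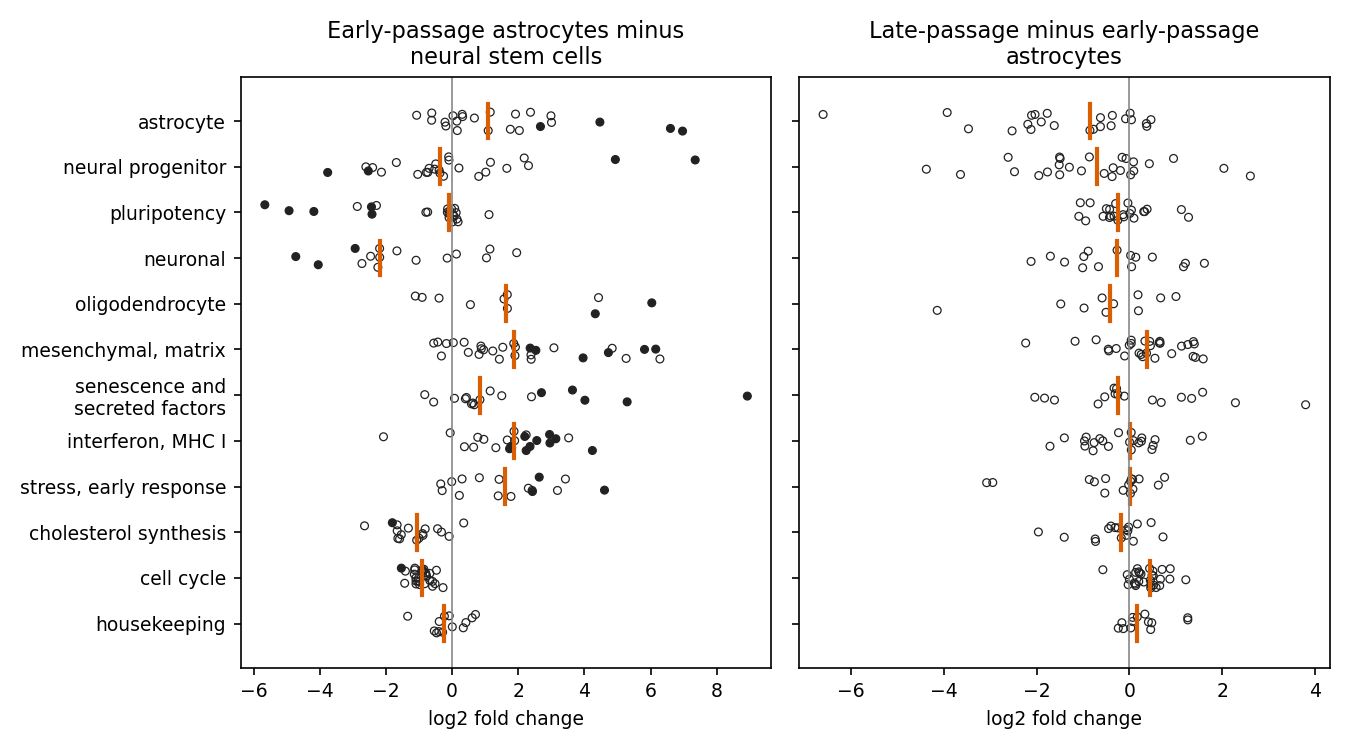
Log2 fold change (horizontal axis) of the measured members of 12 gene lists (rows) in early-passage astrocytes against neural stem cells (left) and in late-passage against early-passage astrocytes (right); each circle is a gene, filled where limma called it, and the orange bar is the list's median. On the left the astrocyte list has a median of 1.09 with 4 filled circles, and on the right a median of -0.85 with 0 filled circles.

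Between neural and pluripotent stem cells, 15 of 23 pluripotency list members fell and 11 of 26 neural stem and progenitor members rose. L1TD1, an RNA-binding protein of pluripotent cells, fell at least 220-fold, from a log2 intensity of 13.23 ± 0.07 (SD, n = 2) to 4.73 ± 0.09 (SD, n = 2), the smallest adjusted p of the comparison (0.000442). The pluripotency factors NANOG and POU5F1 fell at least 26.2-fold and at least 9.54-fold (adjusted p = 0.00294 and 0.00589), and the epithelial adhesion molecules EPCAM and CDH1 fell 113-fold and at least 55.7-fold (adjusted p = 0.00139 for both). The neural transcription factor POU3F2 rose at least 70.5-fold (adjusted p = 0.00108), NR2F1 at least 20.9-fold (adjusted p = 0.00149) and VIM 23.5-fold (log2 4.56 ± 0.29, SE; adjusted p = 0.00139). SOX2, shared by both states, had a log2 difference of 0.18 ± 0.41 (SE, adjusted p = 0.801).

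In all, 1614 genes were called, 766 higher and 848 lower in neural stem cells. With median scaling in place of quantile normalization, 32.7% of the calls were higher instead of 47.5%, as the median of all genes moved to -0.24. Other large rises were those of NCALD (at least 75.1-fold), the membrane proteins EMP1 (at least 42.4-fold) and FLRT3 (at least 38.9-fold), the protease inhibitor A2M (at least 32.3-fold) and the protocadherin PCDH19 (at least 28.2-fold). Large falls were those of the zinc finger genes ZSCAN10 (at least 93.7-fold) and ZFP42 (at least 77.5-fold) and the sodium channel subunit SCNN1A (at least 55.6-fold). The count was 551 without NCRM5 neural stem cells, 516 without H9 neural stem cells and 851 without pluripotent NCRM5 cells. Of 48 named genes called in this comparison, 21 stayed called whichever array was left out, POU3F2, VIM, NR2F1, L1TD1, NANOG, POU5F1, EPCAM and CDH1 among them. A2M was not called without the H9 neural stem cells (log2 4.04, adjusted p = 0.0858), the pluripotent NCRM5 array (adjusted p = 0.131) or the pluripotent H9 array (adjusted p = 0.102), and its log2 change was 8.43 without the NCRM5 neural stem cells. Nor was A2M called without background correction (adjusted p = 0.0986), without a detection filter (adjusted p = 0.0934), with an offset of 50 (adjusted p = 0.0599) or with only the 2 groups compared (adjusted p = 0.0647).

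Of 23 pluripotency members, 15 fell, 0 rose and 8 were not called, with 20 lower adjusted over the list alone. The list had a median of -2.96 (camera adjusted p = 8.46e-14, or adjusted p = 0.208 with an estimated correlation). LIN28A fell 13.5-fold (adjusted p = 0.0182) but remained above background in both neural stem cell lines, at 8.25 in NCRM5 and 10.38 in H9. Of 26 neural stem and progenitor members, 11 rose, among them PAX6 (at least 8.95-fold), NES (4.79-fold), MEIS2 (at least 23.6-fold) and the Notch effector HES5 (at least 10.1-fold), and 1 fell, OTX2. Adjusted over the list alone 14 rose and 1 fell. The median was 1.69, or 1.61 at bounds (adjusted p = 2.56e-05, or adjusted p = 0.208 with an estimated correlation). Of 15 neuronal members, 6 rose, 10 adjusted over the list alone, led by ELAVL3 (25.1-fold), STMN2 (9.25-fold) and TAGLN3 (7.51-fold). All 15 had a positive log2 difference, with a median of 2.00 (adjusted p = 2.56e-05, or adjusted p = 0.273 with an estimated correlation). The astrocyte list was not called (median -0.05, adjusted p = 0.771). VIM and CD44 (3.03-fold) rose, while the lipid carrier APOE (at least 49.8-fold) and PLTP fell (2 higher and 3 lower adjusted over the list alone). CD44 was not called without the NCRM5 (adjusted p = 0.0703) or H9 (adjusted p = 0.192) neural stem cells or the pluripotent NCRM5 (adjusted p = 0.0677) or H9 (adjusted p = 0.0870) array. It was not called either with the mean of its probes (adjusted p = 0.176), without a detection filter (adjusted p = 0.0522) or with only the 2 groups compared (adjusted p = 0.0767). AIF1 and GCLC were not called whichever array was left out (adjusted p between 0.0553 and 0.166 for AIF1 and between 0.0619 and 0.148 for GCLC).

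The remaining lists were not called in this comparison. In the Notch list HES1 was 6.97-fold higher beside HES5, with 4 higher and 1 lower adjusted over the list alone (list adjusted p = 0.274, or 0.0264 without the H9 neural stem cells). The nucleotide enzyme TYMS was 4.48-fold higher in the cell cycle list, also 1 adjusted over the list alone. The cell cycle list (adjusted p = 0.0616) was called higher without the H9 neural stem cells (adjusted p = 0.0232), without the pluripotent H9 array (adjusted p = 0.0249) and without background correction (adjusted p = 0.0228). In the mesenchymal list ACTA2 (13.3-fold), SPARC (5.37-fold) and MMP2 (at least 2.72-fold) were among 4 higher members, with 1 lower (5 and 2 adjusted over the list alone, list adjusted p = 0.581). In the senescence list IGFBP5 was 38.8-fold higher and STC1 8.84-fold lower, the same adjusted over the list alone (list adjusted p = 0.543). BST2, IFITM1 (10.1-fold) and HLA-F (3.51-fold) of the interferon list were lower, also 3 adjusted over the list alone (list adjusted p = 0.0815, or 0.0232 without the H9 neural stem cells).

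HMOX1 (8.10-fold), GPX3 (5.78-fold) and GCLC (4.38-fold), genes of the oxidant response, were lower, also 3 adjusted over the list alone (list adjusted p = 0.189, or 0.000556 without the pluripotent NCRM5 array). Single genes lower in other lists were PDK1 (at least 1.73-fold, glycolysis list adjusted p = 0.146) and MBP (9.66-fold, oligodendrocyte list adjusted p = 0.312), the same adjusted over the list alone. The chaperones HSPA1A (11.8-fold) and HSPB1 (2.83-fold) were lower, also 2 adjusted over the list alone. The stress list had a median of 0.07 and a mean of -0.01 (adjusted p = 0.964). KCNJ8 was 5.70-fold higher (endothelial list adjusted p = 0.600, with 1 higher and 1 lower adjusted over the list alone). In the neural crest list CDH6 was at least 13.0-fold higher and ERBB3 at least 4.06-fold lower, the same adjusted over the list alone (list adjusted p = 0.964). AIF1 of the microglia list was 3.84-fold lower, with 1 higher and 2 lower adjusted over the list alone, and CXCR4 of the mesoderm and endoderm list at least 3.14-fold higher. The cholesterol, HOX and housekeeping lists had 0 members called, also adjusted over the list alone. Cholesterol synthesis (adjusted p = 0.566) was called higher without the pluripotent H9 array (adjusted p = 0.0264), and the HOX list (median 0.47) without the H9 neural stem cells (adjusted p = 0.000399). HOXB2 and HOXB5 had log2 differences of 2.65 ± 1.26 and 2.82 ± 1.61 (SE). The housekeeping list had an adjusted p of 0.568.

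Early-passage astrocytes differed from pluripotent stem cells in more genes than from neural stem cells. LIN28A was at least 201-fold lower and L1TD1 at least 224-fold lower in astrocytes (adjusted p = 0.00117 and 0.000412). Also lower were LIN28B, at least 78.0-fold, and ZSCAN10, at least 95.6-fold. GFAP was at least 46.0-fold higher (adjusted p = 0.000903), CD44 67.1-fold (log2 6.07 ± 0.37, SE; adjusted p = 0.000870), LHX2 at least 91.2-fold and CCL2 204-fold. The homeodomain-only protein HOPX was at least 84.6-fold higher (adjusted p = 0.0152) but was not called without the passage 1 array (adjusted p = 0.0937), the passage 2 array (adjusted p = 0.0826), the pluripotent NCRM5 array (adjusted p = 0.0695) or the pluripotent H9 array (adjusted p = 0.0556). With all 3 astrocyte arrays as 1 group GFAP was not called (adjusted p = 0.102). In all, 2230 genes were called, 1150 higher and 1080 lower. Median scaling gave 33.8% higher calls instead of 51.6%, with the median of all genes at -0.28. The count was 639 without the passage 1 astrocytes, 772 without the passage 2 astrocytes and 1405 without pluripotent NCRM5 cells. Of the named genes called, 26 of 56 stayed called whichever array was left out, GFAP, CD44, LHX2, CCL2, LIN28A and L1TD1 among them. Beside HOPX, AIF1, CDH6, DHCR7, HES1, HES6, MCM3, PAX6, SLC1A3, SNAI2 and TTK were not called whichever array was left out (adjusted p between 0.0525 and 0.228).

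By list, 20 of 23 pluripotency members fell (22 adjusted over the list alone). The median was -4.38, or -4.06 at bounds (adjusted p = 1.45e-15, or adjusted p = 0.208 with an estimated correlation). Of 26 neural stem and progenitor members 10 rose (14 higher and 1 lower adjusted over the list alone), including MEIS2 (at least 52.9-fold), PAX6 (at least 5.53-fold), NES (4.01-fold) and the fatty acid carrier FABP7 (52.6-fold). That list had a median of 1.43, or 1.00 at bounds (adjusted p = 0.000371, or adjusted p = 0.212 with an estimated correlation). Of 23 astrocyte members 9 rose, SLC1A3 (9.15-fold) and VIM (26.2-fold) among them, and 3 fell, APOE, MLC1 and PLTP (9 and 5 adjusted over the list alone). The probes of MLC1 disagreed. The astrocyte call (median 1.10, or 0.78 at bounds, adjusted p = 0.0467) was lost without the passage 2 array (adjusted p = 0.0900), without the pluripotent NCRM5 (adjusted p = 0.0604) or H9 array (adjusted p = 0.190), without background correction (adjusted p = 0.0503) and with an estimated correlation (adjusted p = 0.466).

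Of 29 mesenchymal members 11 rose (16 adjusted over the list alone). POSTN (at least 37.1-fold), the smooth muscle actin ACTA2 (76.9-fold) and the collagen cross-linking enzyme LOX (at least 13.7-fold) were among them. The list's median was 2.03, or 1.76 at bounds (adjusted p = 5.75e-06, or adjusted p = 0.442 with an estimated correlation). The senescence and secreted factor list had 9 of 17 members higher, also 9 adjusted over the list alone, with IGFBP7 (at least 32.6-fold) and IGFBP5 (21.9-fold) beside CCL2. Its median was 2.66, or 1.47 at bounds (adjusted p = 4.80e-05, or adjusted p = 0.212 with an estimated correlation). The interferon list had 8 of 23 higher and 2 lower (10 and 2 adjusted over the list alone). IFI44 (at least 4.95-fold) and IFI44L (at least 3.13-fold) were higher and IFITM1 42.4-fold lower. Here the median was 1.09, or 1.07 at bounds (adjusted p = 0.00138, or adjusted p = 0.695 with an estimated correlation). In the stress list 6 of 16 were higher (7 adjusted over the list alone), the immediate early genes EGR1 (14.1-fold), FOS (11.2-fold) and JUN (9.31-fold) among them. The stress list had a median of 1.29 (adjusted p = 0.00476, or adjusted p = 0.369 with an estimated correlation). In the cholesterol list 4 of 17 were lower, SC5D (6.93-fold), DHCR7 (3.80-fold) and FDPS (2.89-fold) among them (1 higher and 5 lower adjusted over the list alone). Its call (median -1.02, adjusted p = 0.0192) was lost without the passage 1 array (adjusted p = 0.0596), without the pluripotent H9 array (adjusted p = 0.357) and with an estimated correlation (adjusted p = 0.733).

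The other lists were not called between astrocytes and pluripotent cells. The neuronal list had 1 of 15 lower, TAGLN3 (3.51-fold), and 0 adjusted over the list alone (list adjusted p = 0.566). In the oligodendrocyte list PDGFRA was 22.7-fold higher, also 1 adjusted over the list alone (list adjusted p = 0.325). The neural crest list had 4 higher and 1 lower of 8 (4 and 2 adjusted over the list alone), PRRX1 at least 19.5-fold and SNAI2 at least 13.0-fold higher (list adjusted p = 0.312). MCAM was at least 1.73-fold higher, also 1 adjusted over the list alone, in an endothelial and pericyte list with a median of 0.02 and a mean of -0.17 (adjusted p = 0.964). In the cell cycle list BUB1B (3.13-fold), MCM3 (2.55-fold) and TTK (2.55-fold) were lower, with 0 adjusted over the list alone. The cell cycle list (adjusted p = 0.0527) was called lower without the passage 2 array (adjusted p = 0.00385), without the pluripotent NCRM5 array (adjusted p = 0.0144) and without background correction (adjusted p = 0.0291). None of the 9 HOX members was called, also adjusted over the list alone (list adjusted p = 0.566).

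In the Notch list HEY1 (21.3-fold) and HES1 (6.87-fold) were among 3 higher members and HES6 was lower (3.18-fold), the same counts adjusted over the list alone. Its median was -0.59 and its mean 0.15 (adjusted p = 0.896). TXNRD1 was 3.16-fold higher, also 1 adjusted over the list alone (antioxidant list adjusted p = 0.507, or 0.0139 without the pluripotent H9 array). In the glycolysis list SLC2A3 (15.2-fold), HK2 (4.24-fold) and PDK1 (at least 1.77-fold) were lower and 1 member higher, the same adjusted over the list alone (median 0.18, mean -0.28, adjusted p = 0.910). SDHA was 2.53-fold higher, with 0 adjusted over the list alone, in a housekeeping list with a median of -0.10 and a mean of 0.05 (adjusted p = 0.927). AIF1 of the microglia list was 3.11-fold lower, with 2 lower adjusted over the list alone. CXCR4 (at least 3.33-fold) and EOMES (at least 1.38-fold) of the mesoderm and endoderm list were higher, also 2 adjusted over the list alone.

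Late-passage astrocytes were compared with early-passage astrocytes on 1 array against 2, and limma called 0 genes. GFAP was not above background at passage 9, with a log2 intensity of 4.62, against 11.82 at passage 1 and 10.62 at passage 2, a difference of at least 57.9-fold with an adjusted p of 0.120, the smallest of the comparison. At an unadjusted p under 0.05 there were 584 genes, 211 with higher and 373 with lower values, as many as chance would give (584). Without background correction 7 genes were called, DLK1, CRYAB and HLA-DRA lower and IL7R, MMP7, RGCC and SIK1 higher, and with median scaling GFAP alone (adjusted p = 0.0283). The adjusted p of GFAP lay between 0.0283 and 0.291 over the alternatives.

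By camera with its preset correlation, 5 lists differed between the late-passage array and the early-passage arrays, and 0 with an estimated correlation. With 1 late-passage array, its own spread could not be estimated. The astrocyte list lay lower at passage 9, with 18 of 23 members below 0 and a median of -0.85 (camera adjusted p = 1.42e-07, or adjusted p = 0.208 with an estimated correlation). No member was called, and 4 were lower adjusted over the list alone. The cell adhesion protein HEPACAM had a difference of -2.53 ± 0.39 (SE, adjusted p = 0.185) and SLC1A3 one of -2.19 ± 1.00 (SE). CD44 (0.46), VIM (0.02) and GJA1 (-0.08) differed by less than 1 on the log2 scale. The neural stem and progenitor list lay lower as well, with a median of -0.70 (adjusted p = 9.45e-05, or adjusted p = 0.208 with an estimated correlation). None of its 26 members was called, and 3 were lower adjusted over the list alone. PROM1 differed by -4.38 ± 0.80, PAX6 by -3.64 ± 1.16 and NR2F1 by -2.61 ± 0.46 (SE), while SOX2 (-0.86) and NES (-0.54) differed less.

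The cell cycle, glycolysis and mesenchymal lists lay higher at passage 9, with 0 members called, also adjusted over the list alone. In the cell cycle list 25 of 29 members were above 0, with a median of 0.44 (adjusted p = 0.00173, or adjusted p = 0.695 with an estimated correlation). Its call was lost without the passage 1 array (adjusted p = 0.357). In the glycolysis and hypoxia list 18 of 21 were above 0, PGK1 at 1.26 and SLC2A3 at 1.54, with a median of 0.41 (adjusted p = 0.000589, or adjusted p = 0.333 with an estimated correlation). That call too was lost without the passage 1 array (adjusted p = 0.0596). In the mesenchymal list 21 of 29 were above 0, COL5A2 at 1.42 and FBN1 at 1.12, with a median of 0.37 (adjusted p = 0.0308, or adjusted p = 0.703 with an estimated correlation). This call was lost without the passage 2 array (adjusted p = 0.666).

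No other list was called at late passage, and none had a called member. The senescence and secreted factor list had a median of -0.25 and a mean of 0.20 (adjusted p = 0.964), with 1 higher and 2 lower adjusted over the list alone. Among its members CCL2 differed by -1.83 ± 0.42 and IL6 by -2.04 ± 0.55 (SE). The HOX list had a median of 1.46, or 0.79 at bounds (adjusted p = 0.0815), with HOXB4 at 2.01 and HOXB6 at 2.26. The housekeeping list had a median of 0.17 (adjusted p = 0.0815, or 0.0301 without background correction) and the metallothionein list one of -0.54 (adjusted p = 0.113). The interferon list had a median of 0.00 and a mean of -0.18 (adjusted p = 0.507), and lay lower without the passage 2 array (adjusted p = 0.00208). The stress list had a median of 0.00 and a mean of -0.44 (adjusted p = 0.325), with FOS at -3.08 and EGR1 at -2.94. Adjusted p-values were 0.214 for pluripotency, 0.638 for neuronal, 0.312 for oligodendrocyte, 0.325 for endothelial and pericyte, 0.341 for neural crest, 0.696 for Notch and 0.226 for cholesterol synthesis. Members of these lists included CLDN11 at -4.14 ± 1.19 (SE), HEYL at -1.81 and TM7SF2 at -1.96. All these lists apart from the senescence list had 0 members called adjusted over the list alone. Among microglia genes CSF1R differed by 0.86 and CD68 by -0.78. Among mesoderm and endoderm genes EOMES differed by -1.51 and CXCR4 by -1.62, with 1 lower adjusted over the list alone.

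**Figure D3:**
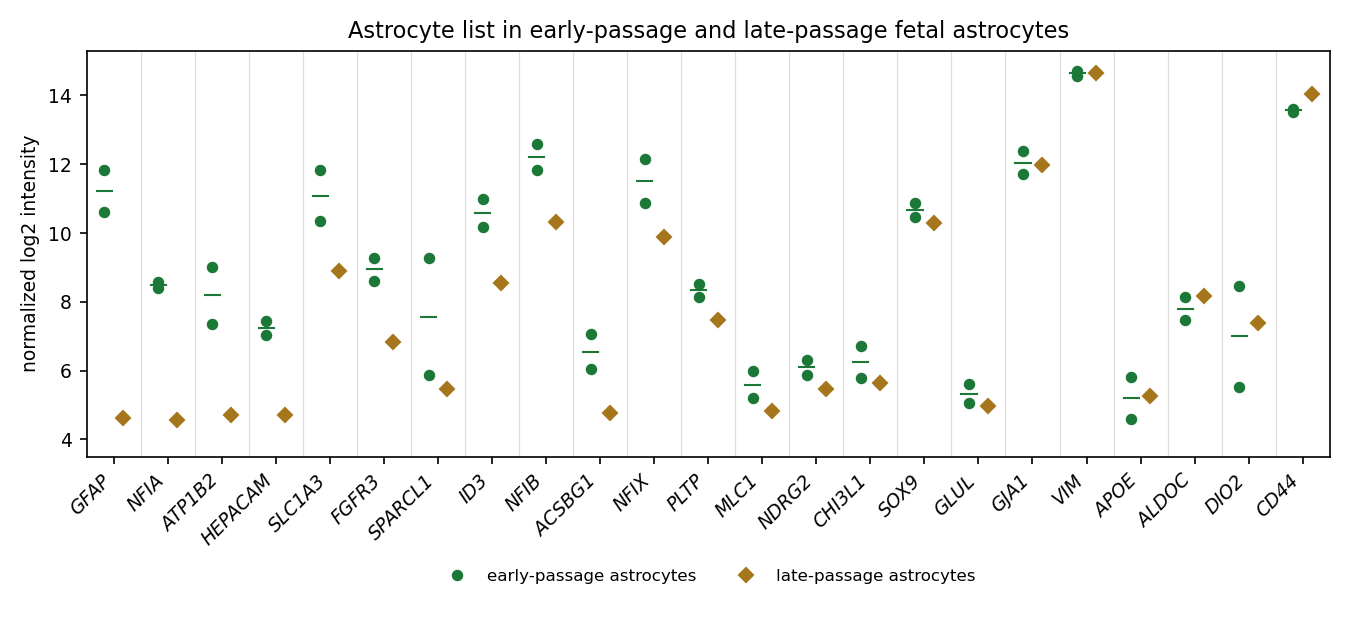
Normalized log2 intensity (vertical axis) of the 23 measured astrocyte list members (horizontal axis, ordered by the late minus early difference) in the 2 early-passage arrays (circles, with a line at their mean) and the late-passage array (diamonds). The late-passage value lies below the early-passage mean for 18 of the 23 genes, with GFAP at 4.62 against a mean of 11.22, and CD44 lies above it.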

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

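All tests in this part were chosen after the results were seen: a first, untested comparison of opposite directions in the lines picked out GFAP, SOX2 and 9 lists and was replaced by a test of the difference itself. The change from pluripotent to neural stem cells was compared between the cell lines NCRM5 and H9 as an interaction in limma with 1 residual degree of freedom, which comes from the 2 early-passage astrocyte arrays. Of 11673 genes 0 were called (907 at an unadjusted p under 0.05, smallest adjusted p 0.272), but 7 of 18 lists differed by camera, and 0 of them with an estimated correlation (the adjusted p was 0.658 for HOX and at least that for the others). Each line and cell type is 1 array, so the p-values assume that these arrays vary like the astrocyte arrays and cannot establish a difference between the lines. The HOX list had a median log2 change of 1.38 in NCRM5 and -0.03 in H9, a median difference of 1.79 (adjusted p = 7.52e-07), with HOXB7 at 9.94 in NCRM5 and 4.35 in H9 neural stem cells. The mesenchymal list had medians of -0.18 in NCRM5 and 0.73 in H9 (median difference -1.27, adjusted p = 0.00139), the endothelial and pericyte list -0.82 and 0.98 (-1.03, adjusted p = 0.0148) and the stress list -0.21 and 0.70 (-0.82, adjusted p = 0.0171). The cholesterol synthesis list (1.14, adjusted p = 0.00658), the metallothionein and antioxidant list (0.38, adjusted p = 0.000201) and the cell cycle list (0.42, adjusted p = 0.0198) had higher median changes in NCRM5. The lines also differ in passage (14 and 8 as neural stem cells), and no explanation was tested.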

How the results depend on the processing

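Counts of called genes moved by more than 1.5 times in 10 of the 14 results that left out an array and in 5 others. For early-passage astrocytes against neural stem cells (555 genes), no filter on detection gave 331, where 19950 genes were tested, and all 3 astrocyte arrays as 1 group gave 886; leaving out 1 array gave 101 to 256. For neural against pluripotent stem cells (1614), fitting only the 2 groups compared gave 931, with fewer arrays to estimate the spread, and leaving out 1 array 516 to 1688. For early-passage astrocytes against pluripotent cells (2230), leaving out 1 array gave 639 to 2359. For the late-passage array (0), no background correction gave 7 and median scaling 1, and leaving out 1 array 0; the cause was not tested. With the replicate number as a block the first comparison gave 417 genes, and with cell line as the pairing block the second gave 1617. The HOX list between early-passage astrocytes and neural stem cells turned with the line left out: its median was 0.33 (adjusted p = 0.0252) without NCRM5 neural stem cells and -0.78 (adjusted p = 0.00165) without H9, the extremes over the arrays left out; the rise or fall of this list therefore rests on 1 line. Of the results for genes called, 1325 kept their call and 130 lost it under the alternatives other than leaving out an array, while 342 kept it and 238 lost it when an array was left out; 0 changed sign while called. Under all the alternatives other than leaving out an array, 26 of 41, 31 of 48 and 33 of 56 named genes stayed called in the first 3 comparisons. Of list calls, 73 were kept and 49 lost, nearly all of the latter with an estimated correlation or fry; when an array was left out 87 were kept and 11 lost, and 15 list results not called became called, over 12 combinations of list and comparison. Signal over background, 3.44 to 5.31 on average, limits folds of dim genes.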

Other observations

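The genes and the MHC class II list of this part, and all its tests, were chosen after the results were seen, and several tests were revised after a first result. LHX2, EMX2 and NR2E1, regulators of the dorsal forebrain and of neural stem cells, were bright in both early-passage astrocyte arrays (NR2E1 9.58 and 10.24) and near the floor in both neural stem cell lines (4.73 and 4.60). NKX2-1 and SIX3, known from the ventral and anterior forebrain, followed the supplier of the astrocytes. NKX2-1 lay at 8.44 at passage 2 and 7.56 at passage 9 from 1 supplier, against 4.38 at passage 1 from the other, and SIX3 at 8.00 and 7.12 against 4.34. These differences were not tested. The neural stem cell lines differed from each other, with HOXB5 (11.08) and HOXB7 (9.94) bright in NCRM5, as in hindbrain or spinal cord, and EN2 (8.62) and GBX2 (8.67), genes of the midbrain and hindbrain border, bright in H9. HOXB2 (9.84 and 9.31) and HOXB5 (8.37 and 8.73) were also bright in the early-passage astrocytes beside LHX2. GDF3, a growth factor of pluripotent cells, went opposite ways in the lines: its log2 change from pluripotent to neural stem cells was 4.53 in NCRM5 and -3.81 in H9 (limma interaction adjusted p = 0.272, not called).

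MHC class II genes were another group looked at. The list held 8 measured genes (HLA-DRA, CD74, CIITA and the HLA-DM, HLA-DO and HLA-DP genes) and did not take in HLA-DRB genes. HLA-DPB2, counted among them, was dim in early-passage astrocytes (4.49 and 4.90). Of the 8 genes, 6 were called higher in early-passage astrocytes than in neural stem cells and 0 lower (median log2 3.67; camera adjusted p = 2.37e-09, over 4 comparisons; adjusted p = 0.0162 with an estimated correlation). They were lower in neural than in pluripotent stem cells (5 of 8 called, median -1.80; adjusted p = 4.90e-05; adjusted p = 0.0314 with an estimated correlation). Between early-passage astrocytes and pluripotent cells 3 were called higher and 1 lower (median 1.61; adjusted p = 0.0271; adjusted p = 0.106 with an estimated correlation). On the late-passage array 7 of the 8 lay below the early-passage mean, CD74 at 6.37 against 9.73 and 10.35 (median -3.08; adjusted p = 2.22e-11; adjusted p = 0.0162 with an estimated correlation), with 0 genes called. Since the list was drawn from these arrays, its p-values are too small to stand alone.

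Microglia in the astrocyte cultures are a candidate source of the MHC class II signal. Of 7 abundant microglial transcripts (TYROBP, FCER1G, C1QA, C1QB, C1QC, LAPTM5 and AIF1), 1 was detected on both early-passage arrays, AIF1. It was brighter in the pluripotent cells (7.94 and 7.48 against 6.47 and 5.68). TYROBP lay at 4.46 and 4.37 where HLA-DRA lay at 11.86 and 12.29. These values argue against microglia only if the microglial probes respond. No array here shows that for TYROBP, FCER1G, C1QB, C1QC and LAPTM5, detected on 0 of the 7 arrays. CD68, CSF1R and CD14 of the fixed microglia list were not in this set. None of them was called against neural stem cells (CSF1R at a log2 difference of 0.91, CD14 at -1.01). Background correction of dim probes was tested in 3 ways. Those calls did not depend on it, since without it 6 of the 8 genes were still called, with a median of 1.81. Its part in the size of the list's difference stays open. The 95% bootstrap interval of that median, 0.237 to 3.18, includes the bound of 0.5 set for it and reflects the spread among the genes. A camera test on genes picked for the pattern decides nothing (limma camera with an estimated correlation, p = 0.00929). An interferon response of the astrocytes, whose interferon list was called higher than in neural stem cells by camera (10 of 23 members, adjusted p = 0.424 with an estimated correlation), and a difference of culture medium stay open and were not tested.

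The lower astrocyte genes of the late-passage array may come from passage, from a different mix of cells or from the array. For GFAP, replacement of the culture by cells lacking the abundant neural genes altogether is argued against. The 10 neural stem and progenitor genes with an early-passage mean of at least 10 differed by a median of -0.95 with an SD of 1.30. GFAP differed by at least -5.85. This test first used the largest fall among the neural genes, that of PROM1 (-4.38), and was then changed to the median. A gene with a mean of 10 cannot fall as far as GFAP before it reaches the lowest detected value of the late-passage array (5.37). Replacement by cells that keep some of these genes therefore stays open. A dimmer array is argued against, since 35.8% of its probes were detected, between the 33.3% and 37.6% of the early-passage arrays. A difference between the 2 cell sources stays open: the astrocyte list differed by a median of -1.08 between passages 9 and 2 of 1 supplier and by -0.07 between the early-passage arrays of both, but each is a difference between single arrays. For the list as a whole (median -0.85) a partial change in the mix of cells cannot be told apart from a change within the cells, because the neural genes shifted about as much; passage itself and a different donor stay open with 1 late-passage array.

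LIN28A, LIN28B, SALL4, DNMT3B and PODXL were higher in neural stem cells than in astrocytes, and undifferentiated cells left in the neural stem cell cultures could bring them. Such cells would carry every pluripotent marker in the same share. Taking dim markers at the lowest detected value, L1TD1, ZSCAN10, ZFP42, EPCAM, CDH1 and NANOG each gave an upper limit per line. All of these but NANOG were among the largest falls between the same arrays, so their limits are low partly by selection. GDF3, which rose in NCRM5 neural stem cells, was not used as a marker. A common share is bound by the tightest limit, that of L1TD1: 0.435% of the pluripotent level in NCRM5 and 0.475% in H9. The loosest limits were 6.29% in NCRM5 (NANOG) and 2.83% in H9 (CDH1). LIN28B, SALL4, DNMT3B and PODXL stood at 15.4% or more in NCRM5 and 8.06% or more in H9, above even the loosest limits. This argues against residual cells that carry all the limit markers at their pluripotent level as the main source of these genes. LIN28A stood at 12.6% in H9. In NCRM5 LIN28A stood at 4.37%, below the limit from NANOG but above those of the other 5 markers (at most 1.21%). The rule set for the test asked that a gene lie above the loosest limit in each line. LIN28A did not meet it in NCRM5, so by that rule the test could not tell. Only against the tightest limit do its shares in both lines argue against residual cells as the main source, each line and cell type being 1 array. The test of residual cells was revised more than once, and LIN28A was set apart, after results were seen. Continued expression in neural stem cells stays as a hypothesis, since it was found and tested on the same arrays.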
